A study of Homo sapiens with 2 samples.

How the data were processed

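Total RNA of 1 control culture and 1 culture treated with ezetimibe for 24 h was sequenced. Per the submitters' processing notes, HISAT2 2.0.4 and StringTie 1.3.0 were used; their settings, the genome build, the annotation and the read depth are not given in the sources used here. The name of the deposited table gives edgeR and KEGG enrichment as the authors' steps. How edgeR was run on 1 library per condition, and at which threshold, is not given in the sources used here. No value per library or per gene was analysed here.

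Per the file headers, the deposited table gives for each of 327 pathways the changed genes, split into up and down, the background genes, an enrichment ratio called the rich factor, a p-value and a q-value. The name of the table sets ezetimibe against control, so up was read as higher after ezetimibe; no value in the table can check this order. The authors' rich factor is the share of changed genes that lie in a pathway over the share of background genes that do, and recomputing this ratio from the deposited gene numbers gave the same values (largest difference 4.88e-15). The authors' p-values did not match a one-sided hypergeometric test on the same numbers: that test gave a smaller p in 215 of the 218 pathways with a rich factor above 1. The authors' p was 1 in 110 pathways, including all 109 with a rich factor below 1. The authors' q-value lay within 1% of the p-value times the number of pathways over its rank in 324 of 327 pathways, without the step that keeps q in the order of p. The authors' p and q are therefore printed as theirs. Both take genes as independent units.

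Fixed before the data were examined were 35 gene lists, 61 KEGG pathways of interest and the rule for named genes. Of the pathways, 59 are in the table and 2 are not. The named genes are NPC1L1, the listed members of lists with 12 or fewer members, the 12 genes under the most pathways in each direction, and up to 4 members under the most pathways from each list with 3 or more listed members. Some genes that this rule takes are not reported here. Named pathways are the 10 with the smallest authors' p and those of interest with an authors' p below 0.05. List symbols were matched to the table through Ensembl gene IDs, which also carries older symbols. Of 631 list members 274 are listed, and 24 members are in more than 1 list. The plan allowed for fold changes per gene; as the table has none, the part of the plan for tables that list changed genes alone was used, and no size rule was applied.

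For each list the members listed as up and down were counted, with an exact Clopper-Pearson 95% interval of the share up. The directions were then reassigned 10000 times among the listed genes, and a list with 3 or more listed members stood apart when fewer than 250 draws were as extreme on one side. The plan had random draws for tables with values per gene only. For tables of changed genes it had the counts and Fisher's exact test of each split, so the draws and their limit depart from it. Fisher's exact test was computed as a description of the list and is not printed, since genes are not replicates. For pathways the interval was compared with the share over all genes. Intervals and draws describe counting among these genes and leave out the spread between cultures.

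GC content, transcript length (of the longest transcript) and gene span were taken from GENCODE release 29 by gene ID for 2237 of the 2238 genes; the authors' annotation may differ from it. Matched draws, added after the data were seen, reassigned directions within 10 GC classes split into 5 length classes each; draws matched on GC content alone and on GC content and gene span were also made. On simulated directions that followed the observed GC trend over 2237 genes, 97 of 100 lists of 12 genes with a probability of 0.9 of being up were found by draws from all genes, and 95 by matched draws. Of 100 such lists with a probability of 0.05, 50 and 44 were found, so lists of this size that lean down are missed often. Of 100 unshifted lists of GC-rich genes, 49 were called up by draws from all genes, and 0 were called up and 3 down by matched draws. The other alternatives were stricter authors' thresholds, the recomputed hypergeometric test, smaller pathway sets, and leaving out shared members or widely annotated genes. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.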

Results

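RNA from SNU-449 cells, a human hepatocellular carcinoma line, was sequenced after culture without drug and after 24 h with ezetimibe, a cholesterol-lowering drug that blocks the sterol transporter NPC1L1. There was 1 control library and 1 ezetimibe library, so no difference has a replicate check, and all statements describe these 2 libraries. The authors' deposited table lists the genes called changed between them under 327 KEGG pathways, each gene with a direction and no level, fold change or p. It holds 2238 distinct changed genes, which is 25.2% of its background of 8877 pathway genes. Of these genes, 728 were listed as up and 1510 as down after ezetimibe, a share up of 32.5% (exact Clopper-Pearson 95% interval 30.6 to 34.5, counting error only). Up is read as higher after ezetimibe from the order of the names in the comparison, which no value in the table can check. Sequencing depth is unknown from this table. A gene that is not listed was unchanged by the authors' criteria, not expressed, or outside the pathways.

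The comparison asked which genes differed after ezetimibe. NPC1L1 itself (ENSG00000015520; chromosome 7, 44512535 to 44541315, minus strand, GENCODE release 29 on GRCh38) was listed as up. Among genes listed as up, those under the most pathways included the MAP kinase kinases MAP2K1, under 80 pathways, and MAP2K2, under 68, and the NF-kB subunits NFKB1 and RELA, under 64 each. Others were the AP-1 subunit JUN (49), the adenylyl cyclase ADCY8 (48), the cytokine IL6 (43), the cell cycle inhibitor CDKN1A (41), the NF-kB inhibitor NFKBIA (41), FOS (36) and the phospholipase PLCG2 (35). Among genes listed as down, the phosphoinositide 3-kinase subunits PIK3CA (90), PIK3R1 (87) and PIK3R3 (87) and the kinase AKT1 (85) were among those under the most pathways. The protein kinase PRKACB was under 67 pathways, PRKCA under 65, the stress kinases MAPK9 under 60 and MAPK10 under 59, and the phospholipase PLCB3 under 51. The number of pathways reflects how widely a gene is annotated and not the size of its change.

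The listed genes of cholesterol synthesis, 12 of the 25 in the fixed list, were mostly up. Of the 12 listed members of the SREBP2 target list, 10 were up (83.3%, 95% interval 51.6 to 97.9), among them the later enzymes of the pathway CYP51A1 and DHCR7. The sterol isomerase EBP, named after its direction was seen, was among the 2 members listed as down. In 6 of 10000 draws that reassigned the directions among all genes, the list held as many up members, and in 5 of 10000 draws matched on transcript GC content and length. Of the 6 listed genes of sterol uptake and transport, 4 were up, including NPC1L1 and the lysosomal cholesterol exporters NPC1 and NPC2, and the lipoprotein receptor SCARB1 and caveolin CAV1 were down; 912 draws held as many up, so this list did not stand apart. By KEGG pathway, Terpenoid backbone biosynthesis, the early part of sterol synthesis, had 4 genes up and 5 down (44.4% up, 13.7 to 78.8), and Cholesterol metabolism, which also holds lipoprotein genes, 4 up and 10 down (28.6%, 8.39 to 58.1). Of the LXR target and efflux list, the nuclear receptor NR1H2 was up and the exporter ABCG1 and the ubiquitin ligase MYLIP were down. The 4 listed genes of fatty acid synthesis were all down (ACACB, ACSL3, ELOVL6 and FADS2), and 2110 draws held as few up. A list with 4 listed members could not stand apart downward in these draws, so they cannot decide. Of 6 listed genes of fatty acid oxidation, 4 were down (EHHADH, PPARGC1A, ACADM and CPT2) and 2 up, close to the 1.94 expected up from all genes.

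The listed members of the fixed lists of endoplasmic reticulum (ER) stress and of the integrated stress response were up with 1 exception. Of the 23 and 25 members of these lists, 12 and 17 were listed. All 12 listed members of the list of the unfolded protein response and ER chaperones were up (95% interval 73.5 to 100%), including the stress sensors EIF2AK3 (PERK) and ERN1 (IRE1) and the chaperones HSPA5 (ENSG00000044574; chromosome 9, 125234853 to 125241330) and CALR. Of 17 listed genes of the integrated stress response, 16 were up (94.1%, 71.3 to 99.9), including the transcription factor ATF4 itself (ENSG00000128272; chromosome 22, 39519695 to 39522685), VEGFA, the mitochondrial serine enzyme SHMT2 and the cysteine-producing enzyme CTH. The exception, named after its direction was seen, was the amino acid transporter SLC7A5. For both lists, 0 of 10000 draws from all genes and 0 of 10000 matched draws held as many up members. The listed members of the short autophagy and lysosome lists, 5 of 21 and 10 of 19, went the same way. The wider KEGG pathways also held more genes listed as up than the 32.5% of all genes, with 27 up and 29 down for Autophagy and 28 up and 22 down for Lysosome. All 5 listed members of the autophagy list were up (47.8 to 100%; SQSTM1, ATG16L1, WIPI1 and MAP1LC3B among them), as were all 10 listed members of the lysosome list (69.2 to 100%), including the proton pump subunits ATP6V0D1 and ATP6V1H, the protease CTSL and the hexosaminidase HEXA. As many were up in 42 and 0 of 10000 draws, and in 201 and 9 of the matched draws.

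The listed members of the fixed lists of cell division and DNA replication, 20 of 26 and 22 of 25, were all down. All 20 listed members of the cell cycle list were down (share up 0%, 95% interval 0 to 16.8). They included cyclin D1 CCND1 (ENSG00000110092, chromosome 11, 69641087 to 69654474), the transcription factor E2F1, the kinase CDK2 and cyclin E1 CCNE1. All 22 listed DNA replication genes were down (0 to 15.4%), including the polymerase clamp PCNA (ENSG00000132646; chromosome 20, 5114953 to 5126626), the ribonucleotide reductase subunits RRM1 and RRM2 and the polymerase subunit POLD1. Draws from all genes held as few up members in 5 and 4 of 10000 cases, and matched draws in 0 and 0.

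The listed members of the fixed lists of NF-kB and cytokine genes and of immediate early genes were mostly up. Of 15 listed NF-kB and cytokine genes, 13 were up (86.7%, 59.5 to 98.3), including NFKB1, IL6, NFKBIA and the neutrophil chemokine CXCL8. The chemokines CCL2 and CXCL6, named after their direction was seen, were down. Of 12 listed immediate early genes, 11 were up (91.7%, 61.5 to 99.8), including JUN, FOS, MYC and EGR1, and the phosphatase DUSP4, also named afterwards, was down. As many were up in 0 and 0 of 10000 draws from all genes, and in 1 and 144 matched draws. By KEGG pathway, Toll-like receptor signaling had 17 genes up and 20 down (45.9% up, 29.5 to 63.1) and NOD-like receptor signaling 23 and 32 (41.8%, 28.7 to 55.9). Their intervals included the overall share of 32.5%, but only 249 and 175 matched draws held as many up, so both stood apart upward in matched draws. Chemokine signaling had 17 up and 29 down (37.0%, 23.2 to 52.5) and did not stand apart in either way. The interferon list had 1 of 6 members up (IRF7) and the RNA sensor DDX58, OAS1 and MX1 among those down; 3636 draws held as few up.

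**Figure D1:**
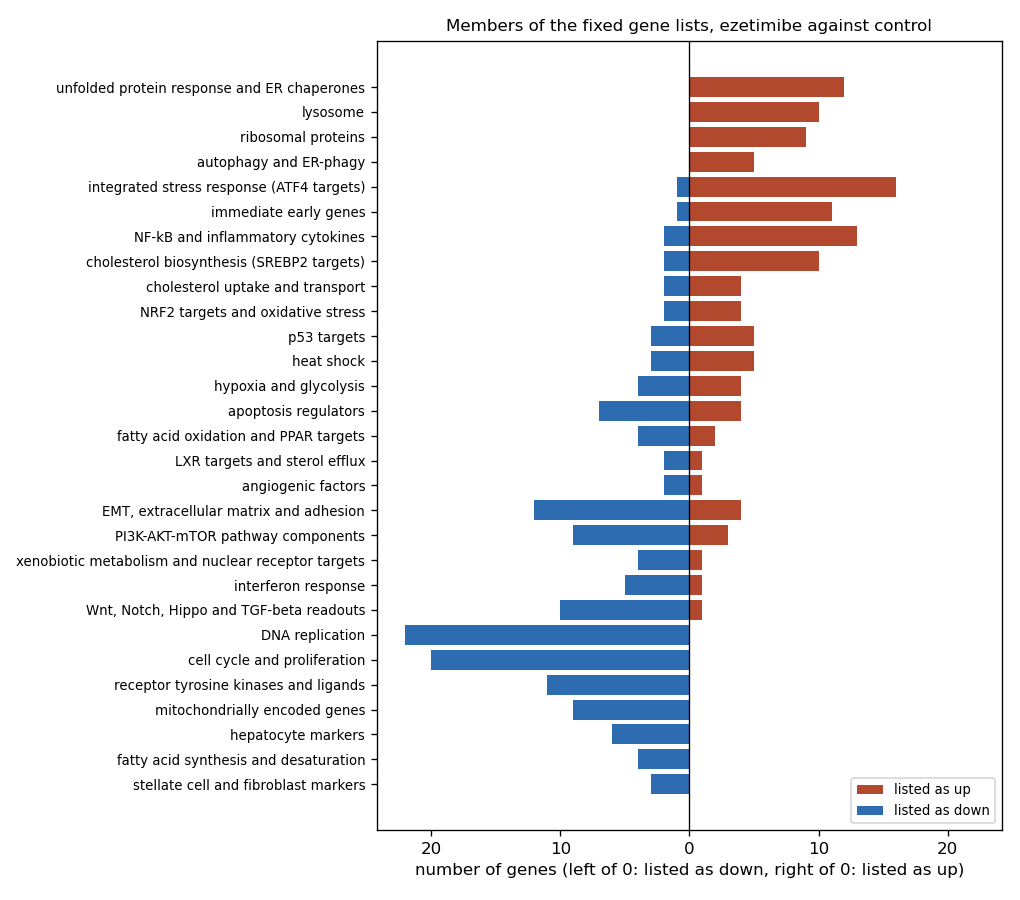
Number of members of each fixed gene list that the authors' deposited table gives as up (red, right of 0) or down (blue, left of 0) in the ezetimibe library against the control library, for the 29 lists with 3 or more listed members. The list of the unfolded protein response and ER chaperones has 12 up and 0 down, and the DNA replication list has 0 up and 22 down.

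The listed members of the fixed list of growth factor receptors and ligands were down. All 11 were down (share up 0 to 28.5%), including the insulin-like growth factor receptor IGF1R, the hepatocyte growth factor receptor MET, the ligand TGFA and the receptor FGFR3; 132 of 10000 draws and 92 matched draws held as few up. Of 12 listed components of the PI3K, AKT and mTOR pathway, 3 were up and 9 down, PIK3CA, PIK3R1 and AKT1 among the latter, which did not stand apart from draws (4107 held as few up). Readouts of Wnt, Notch, Hippo and TGF-beta signalling had 1 of 11 members up and TGFB2, WNT5A, BMP4 and ID1 among those down (9.09%, 0.23 to 41.3). As few were up in 809 draws from all genes and in 102 matched draws, so this list stood apart in matched draws only. Of 16 listed genes of extracellular matrix, adhesion and epithelial-mesenchymal transition, 4 were up, including the gelatinase MMP9, and 12 down, including the integrin ITGB1, E-cadherin CDH1 and thrombospondin THBS1 (3630 draws held as few up). Of 3 listed angiogenic factors, VEGFA was up and PDGFB and NRP1 were down.

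Several stress and metabolic lists were split. Of 8 listed p53 targets, 5 were up, including CDKN1A, GADD45A and the BH3-only gene BBC3, and the death receptor FAS was down (812 draws held as many up). Of 11 apoptosis regulators, 4 were up, including the pore former BAK1, and BCL2 and CASP8 were among the 7 down. Of 9 paraptosis regulators, 1 was listed, MAPK9, as down. NRF2 targets had 4 of 6 up, including the haem oxygenase HMOX1 and TALDO1, with AKR1B10 and the exporter ABCC2 down. Heat shock genes had 5 of 8 up, including HSPA6, with the chaperone HSP90AA1 down; HSPA1A and HSPA1B were also up but are near-identical copies and uncertain. Of 8 hypoxia and glycolysis genes, 4 were up, including VEGFA and the glucose transporter SLC2A1, and 4 down, including LDHA and PGAM1. Of 5 xenobiotic metabolism genes, CYP1A1 was up and UGT1A6, UGT2B7 and CYP1B1 were among the 4 down. None of these lists stood apart from draws, and those with few listed members could not do so downward. No metallothionein was listed.

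All 9 listed ribosomal protein genes were up (95% interval 66.4 to 100%; RPL4, RPL10, RPL13 and RPL18 among them), in 1 of 10000 draws and 33 matched draws; their many processed copies in the genome leave single members uncertain. All 9 listed members of the mitochondrially encoded list, each a messenger RNA, were down (0 to 33.6%; MT-CO1, MT-CO2, MT-CYB and MT-ATP8 among them). As few were up in 295 draws and 364 matched draws, so this list did not stand apart, except in draws matched on GC content and gene span (238). Of nuclear genes of oxidative phosphorylation, 2 were listed, both as down. All 6 listed hepatocyte markers were down (CPS1, FGA, FGB and FGG among them; 930 draws held as few up), as were the cholangiocyte markers SPP1 and SOX9 and the fibroblast markers COL1A1, COL1A2 and ACTA2. Of immune cell markers 1 was up and 1 down, and no endothelial marker was listed. In all, 8 of the 29 lists with 3 or more listed members stood apart upward, 3 downward and 18 in neither direction. Lists with 9 or fewer listed members could not stand apart downward in draws from all genes, since 295 draws held 0 of 9 up. For such lists the lack of a downward call carries no information. Without any trend an expected 1.45 of 29 at most would stand apart by chance; draws from all genes call more where a list is rich in GC, as in simulated unshifted lists of GC-rich genes, of which 49 of 100 were called up.

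The direction of a gene went with the base composition and length of its transcript. Genes listed as up had a median GC content of 55.2% in their longest transcript, against 43.6% for genes listed as down. The share listed as up was 3.12% in the 10% of genes with the lowest GC content (1.27 to 6.33) and 63.4% in the 10% with the highest (56.7 to 69.7). Median transcript length was 2860 bases for genes listed as up and 4401 for those listed as down, and median gene span 17892 and 52751 bases. On chromosome 19, where the median GC content of listed genes was 60.0%, 67.2% of 119 genes were listed as up, against 12.9% of 116 genes on chromosome 4, with a median of 41.1%. The matched draws, given for the lists that stood apart and for some others, hold this trend fixed.

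**Figure D2:**
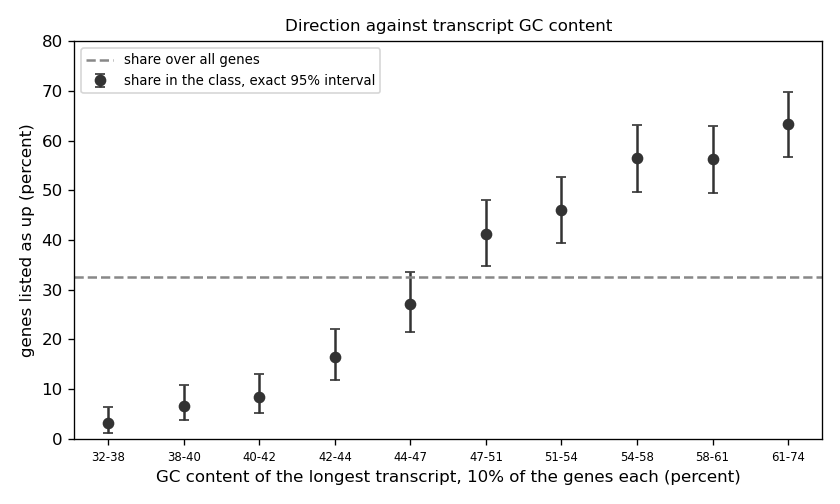
Percent of genes listed as up (vertical axis) in 10 equal classes of the listed genes ordered by the GC content of their longest GENCODE transcript (horizontal axis, range of each class in percent). Points are shares with exact Clopper-Pearson 95% intervals, and the dashed line is the share over all genes, 32.5%; the share goes from 3.12% in the lowest class to 63.4% in the highest.

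The pathways most enriched among the changed genes were those of cell division. In the authors' deposited table the Cell cycle pathway led, with 8 genes up and 73 down of 129 (rich factor 2.49, p = 8.97e-13, q = 2.93e-10), followed by DNA replication with 1 up and 27 down of 37 (p = 4.23e-07). The next in the authors' deposited table were Small cell lung cancer (14 up, 40 down; p = 6.47e-07), Hepatocellular carcinoma (21 up, 59 down; p = 2.62e-06) and Pathways in cancer (58 up, 143 down; p = 2.86e-06). Then the authors' deposited table has p53 signaling (10 up, 31 down; p = 5.29e-06), Hippo signaling (11 up, 61 down; p = 6.19e-06), the Fanconi anemia pathway of crosslink repair (1 up, 33 down; p = 6.58e-06), Axon guidance (16 up, 64 down; p = 1.02e-05) and Colorectal cancer (14 up, 31 down; p = 1.49e-05). An authors' p below 0.05 was given to 88 of 327 pathways in the authors' deposited table, 31 of them disease pathways. These p-values take genes as the unit and describe the list from 2 libraries, not the effect of the drug across cultures. They also stand on a test that is not given in the sources used here.

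Of the 59 pathways of interest in the table, 22 had an authors' p below 0.05 in the authors' deposited table, and their members were split by direction. Protein processing in endoplasmic reticulum had 49 genes up and 25 down (66.2% up, 54.3 to 76.8), Autophagy 27 and 29 (48.2%, 34.7 to 62.0), Lysosome 28 and 22 (56.0%, 41.3 to 70.0), IL-17 signaling 24 and 17 (58.5%, 42.1 to 73.7) and Steroid biosynthesis 7 and 3 (70.0%, 34.8 to 93.3), all with intervals above the 32.5% of all genes. TNF signaling had 23 up and 26 down (46.9%, 32.53 to 61.7), above the overall share by its interval but not apart in matched draws (298 of 10000 held as many up). On the other side, Cell cycle had 9.88% up (4.36 to 18.5), DNA replication 3.57% (0.0904 to 18.3), Hippo signaling 15.3% (7.88 to 25.7), Focal adhesion 16.2% (8.95 to 26.2), ECM-receptor interaction 13.5% (4.54 to 28.8) and TGF-beta signaling 16.2% (6.19 to 32.0). Regulation of actin cytoskeleton had 15 up and 56 down (21.1%, 12.3 to 32.4), but 1996 matched draws held as few up. Without genes under more than 20 pathways, the intervals of TNF signaling, TGF-beta signaling and Regulation of actin cytoskeleton included the overall share.

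By interval, no such lean was seen for the other pathways of interest with an authors' p below 0.05, whose intervals included the overall share. They were Apoptosis (27 up, 37 down), MAPK signaling (45 and 66), PI3K-Akt signaling (33 and 86), Wnt signaling (15 and 48), FoxO signaling (16 and 37), mTOR signaling (22 and 39), Ferroptosis (9 and 8), p53 signaling and Hepatocellular carcinoma. In draws matched on the mean GC content of all transcripts, Hepatocellular carcinoma (100 draws) and Wnt signaling (245) stood apart downward. In draws matched on GC content and length they did not (796 and 408). Among pathways of interest with a larger authors' p, Ribosome had 34 genes up and 3 down, Cytokine-cytokine receptor interaction 33 and 33, Mitophagy 15 and 9, and NF-kappa B signaling 18 and 17, with intervals above the overall share. Ribosome (rich factor 0.824) and Cytokine-cytokine receptor interaction (0.777) were not enriched. They held fewer changed genes than their share of the background. For NF-kappa B signaling, 1401 matched draws held as many up, and its interval included the overall share without genes under more than 20 pathways. ABC transporters, the ATP-driven export pumps, had 0 up and 18 down, and Fatty acid metabolism 2 up and 19 down, with intervals below it. Altogether, by their intervals, 10 of the 59 pathways leaned up, 9 down and 40 neither way. Pathways share genes, so these are not separate results, and no number expected by chance was worked out for them. Of these 40, Toll-like receptor and NOD-like receptor signaling stood apart upward, and Neuroactive ligand-receptor interaction (14 up, 47 down; 55 draws) downward, in matched draws only. The rich factor was below 1 for NOD-like receptor signaling (0.974) and Neuroactive ligand-receptor interaction (0.668).

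**Figure D3:**
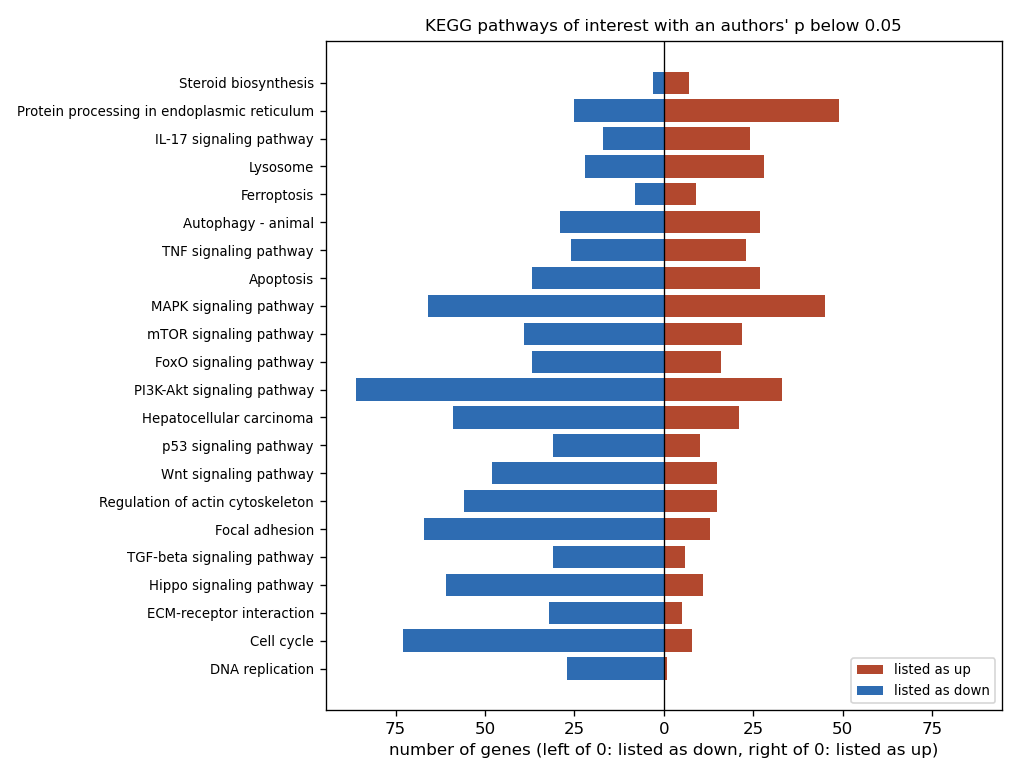
Number of genes that the authors' deposited table gives as up (red, right of 0) or down (blue, left of 0) in the ezetimibe library against the control library, for the 22 KEGG pathways of interest with an authors' p below 0.05, ordered by share up. Protein processing in endoplasmic reticulum has 49 up and 25 down, and Cell cycle 8 up and 73 down.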

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

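The matched draws, the subsets of the overall split, the adjusted hypergeometric count and the GC alternatives were chosen after the data were seen; the other settings were planned. The share of genes listed as up was 32.5% over all genes and 35.8% among genes under 1 pathway only, where the cause was not tested, and it stayed within its interval in the other 3 subsets. The 88 pathways with an authors' p below 0.05 became 53 with the authors' q below 0.05, 55 with p below 0.01, and 57 without human disease pathways; each of these settings is stricter or takes fewer pathways. The recomputed hypergeometric test gave 115 pathways at p below 0.05 and 77 after Benjamini-Hochberg adjustment; with that test and adjustment, genes listed as up alone gave 23 and genes listed as down alone 75. Pathways with at least 5 changed genes gave 88. All 11 lists that stood apart kept their direction without shared members and with each of the 4 kinds of matched draws. These settings gave 11 to 13 lists. They take each list alone and make no allowance for the number of lists compared. Of the 19 pathways of interest that leaned, 15 kept their direction without genes under more than 20 pathways and 16 with matched draws, which also set Toll-like receptor and NOD-like receptor signaling apart upward and Neuroactive ligand-receptor interaction downward, 19 in all. The difference in share up between the GC-richest and GC-poorest 20% of genes was 54.9 percentage points, and 55.6 with the mean GC content of all transcripts. Other fold thresholds, floors, pseudocounts, scalings and a stricter adjusted p per gene were not run, since the table gives no value per gene. No paired analysis was possible because each condition has 1 library. Depth is unknown, so what it limits cannot be stated.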

Other observations

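The gene groups of the next paragraph and all tests in this part were chosen after the data were seen. The draws of the next paragraph take each group or pathway alone and make no allowance for that choice, so they only describe it. For the test without the described groups, its own result had not been seen when it was set out.

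Beyond the fixed list, all 29 listed cytosolic ribosomal protein genes, grouped by name, were up, including RPS27, RPL37A and RPLP1. Draws matched on GC content and length gave 14.8 expected up. Most ribosomal genes are not listed: the Ribosome pathway has 37 changed genes of 178 in the background. This group left out RPS27L and RPL22L1. Mitochondrial ribosomal proteins (2 up, 2 down), histones (5 and 9), integrins (1 and 10) and frizzled receptors (0 and 5) were also grouped. None of these stood apart, and the smaller groups could not do so downward. The MCM helicase subunits had 0 up and 6 down, with as few up in 247 matched draws. The mitochondrial 12S ribosomal RNA MT-RNR1 was listed as up while the 9 listed mitochondrial messenger RNAs were down; nuclear copies of mitochondrial genes leave both uncertain. Subunits of the V-ATPase, the proton pump that acidifies lysosomes, were up in 9 of 11 cases, and they make up 9 of the 12 genes listed as up under Oxidative phosphorylation, so that pathway's split mixes the pump with the respiratory chain. Of 9 listed cytosolic aminoacyl-tRNA synthetases, 8 were up (AARS, CARS, FARSA, GARS, SARS, VARS, WARS and YARS) and LARS was down, and 44 of 10000 matched draws held as many up. The 3 listed mitochondrial ones were down, a group too small to stand apart downward (6548 matched draws held as few up). Among DNA repair pathways, Mismatch repair had 0 up and 16 down, Homologous recombination 1 up (TOP3A) and 26 down, Base excision repair 1 up and 15 down, and Nucleotide excision repair 2 up and 20 down, with as few up in 22, 60, 15 and 99 of 10000 matched draws. How many of these genes also lie in the DNA replication pathway was not examined. The repair pathways may therefore in part recount the replication genes. Non-homologous end-joining, with 1 up and 6 down, did not stand apart (5106 matched draws).

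Genes listed as up had GC-richer transcripts, with 54.9 percentage points between the share up in the 20% of genes with the highest and the 20% with the lowest GC content. Gene length alone is argued against: in each of 5 classes of transcript length and each of 5 classes of gene span, the highest of 3 GC classes exceeded the lowest in share up, by at least 20.6 percentage points for length (bootstrap 95% interval 12.6 to 28.0) and 25.3 for span (18.0 to 33.3). The described gene groups do not carry it either, since without every list and pathway of interest that stood apart the difference over the remaining 1559 genes was 56.4 percentage points (50.3 to 62.5). A GC-dependent difference between the 2 libraries, from RNA quality, amplification or sequencing, may underlie the trend, and so may a response of the cells that follows GC content. With 1 library per condition these cannot be told apart.

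The listed members of the ER chaperone, ATF4 target, lysosome and cholesterol synthesis lists were almost all up. Listed were 12 of 23, 17 of 25, 10 of 19 and 12 of 25 members, in that order. Of these, 12, 16, 10 and 10 were up, and members that are not listed have no direction here. These lists were singled out after their splits were seen. Each was therefore set against the rarest split, in either direction, among all 29 fixed lists in each draw matched on GC content and length. A split as rare as theirs occurred in some list in 0, 0, 95 and 39 of 10000 draws, in that order, which argues against the GC content and length trend as the whole cause. A response of the cells to ezetimibe stays open as a hypothesis, and so does any other difference between the 2 cultures, such as density, medium or handling, which 1 culture per condition leaves untested.

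The cell cycle and DNA replication lists had 0 genes listed as up. By the same comparison over all 29 lists, a split as rare occurred in 0 and 0 of 10000 matched draws, which argues against the GC content and length trend as the whole cause for the cell cycle list and the DNA replication list. Lower proliferation in the treated culture is a hypothesis that these directions leave open, as is a difference in culture density between the 2 cultures. Neither was tested. The comparison over all 29 lists was not run for the autophagy, NF-kB and cytokine, immediate early, growth factor receptor and ribosomal protein lists. Their matched draws, 201, 1, 144, 92 and 33 of 10000 in that order, take each list alone. For these lists the GC content and length trend was therefore not tested with allowance for the choice among lists.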
